A study of Mus musculus with 33 samples.

How the data were processed

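RNA from mouse liver was measured on Affymetrix arrays at 12 months of age. Per the labels, total RNA was taken with Trizol, and 5 ug of it gave the biotin-labelled cRNA that was hybridised. The 33 columns of the table are 21 arrays of 4 groups: 7 wild-type livers (wt), 5 livers of E2f3a knock-out mice (3aKO), 5 tumours of E2f1 knock-in mice (1KI) and 4 tumours of E2f3b knock-in mice (3bKI). The wt and 3aKO livers are labelled normal, and the tumours are labelled as hepatocellular carcinoma that arose spontaneously. Every wt and 3aKO array appears in the table once in each of 2 normalizations, with the 1KI arrays in normalization 1 and with the 3bKI arrays in normalization 2.

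The deposited values are log2 expression values per probe set, summarised and normalized by the authors in those 2 separate runs by a method that the labels do not state. Across the 12 arrays held in both runs, the values of the same array correlated across probe sets with r of 0.9989 to 0.9990, and the median shift between the runs was -0.110 to -0.108. The number of arrays per group limits the precision of every value.

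Of the 45101 probe sets, 64 are array controls, 34945 carried 1 gene symbol in the annotation used here, 932 carried several and 9160 carried none. Probe sets with 1 symbol were kept, and each gene was represented by its probe set with the highest mean over all columns, which left 18193 genes. A choice between probe sets was made for 9010 genes. No genome coordinates are given here. Gene order along the chromosome of E2f3 came from a RefSeq gene table and was used only to say which genes are neighbours.

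The comparisons were 3aKO vs wt, 1KI vs wt and 1KI vs 3aKO in normalization 1, and 3bKI vs wt and 3bKI vs 3aKO in normalization 2. The 2 tumour groups share no normalization and were not compared directly. Each comparison was fitted on its own 2 groups with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. P values were two-sided and adjusted by Benjamini-Hochberg over the 18193 genes, and a gene counted as higher or lower at an adjusted p under 0.05. Errors after a log2 change are moderated standard errors (SE), and errors after a group mean are standard deviations (SD).

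Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. The lists hold 721 genes, of which 649 were measured. They cover DNA replication and G1/S, mitosis and G2/M, the E2F and pocket protein family, DNA repair and checkpoint, p53 targets, oncofetal and hepatocellular carcinoma markers, hepatocyte secretory and identity genes, bile acid synthesis and transport, urea cycle and amino acid catabolism, the pericentral and Wnt pathway, fatty acid synthesis, cholesterol synthesis, PPARalpha and fatty acid oxidation, xenobiotic cytochrome P450, NRF2 and glutathione, glycolysis and hypoxia, endoplasmic reticulum stress, the acute phase response, the interferon response, male-biased and female-biased liver genes, the circadian clock and immediate early genes. Marker lists cover macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, endothelium, stellate cells and fibrosis, cholangiocytes, erythroid cells, pancreas acini, and adipocytes and skeletal muscle. Some lists share genes, so their results are not independent. Beside each camera call of the fits given first stands the adjusted p with an estimated correlation, and beside the count of members called over all genes stands the count adjusted over the list alone. In the alternatives the correlation was estimated only with a sex covariate, without the array of unclear sex.

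Genes named in the text followed a rule: E2f1 and E2f3, the genes with the largest increase or decrease among those called with no overlap between the groups, and in each list the called members with the largest change, or the members of lowest p where none was called. Predicted genes and immunoglobulin segments were left out of the ranking by size. Genes named outside the rule are marked as chosen after their values were seen.

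The labels give no sex, and the sex of each animal was read from Xist (log2 above or below 10) and the mean of 3 Y-linked genes (above or below 5). This gave 3 females and 4 males in wt, 3 females and 2 males in 3aKO, 2 females and 3 males in 1KI, and 3 females and 1 array of unclear sex in 3bKI. The log2 ratio of the 3' to the 5' control probe set of beta-actin was taken per array as a sign of RNA quality, and that of GAPDH as a second one. A higher ratio stands for less intact RNA.

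The lists, the tests, the rule for named genes and the following alternatives were chosen before the data were examined: quantile normalization, centring of each array, a filter on the 40% of genes with the lowest mean, the mean of the probe sets of a gene, a test of every probe set, a fit with all 3 groups of the normalization, eBayes with trend and robust, array weights, the replicate number as a block, sex as a covariate for genes where the groups hold both sexes, the other normalization, a threshold of 0.01, an estimated correlation and leaving out each array in turn. Added after the data were seen were fits within a sex, the sex covariate for 3bKI and for lists with the treatments of the array of unclear sex, the beta-actin ratio as a covariate, and fits with wt replicates 6 and 7 or 1KI replicates 3 and 4 left out or used alone. No array was left out of the values given first.

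The procedure was tested on simulated data of the same size. Noise was normal and independent between genes and arrays, at the within-group spread of each gene, with no sex effect and no outlying array. All measured genes of 1 list were also shifted by 1. With 100 genes shifted by 1 on the log2 scale in each comparison, 97 were recovered for 3aKO vs wt, 91 for 1KI vs wt, 89 for 1KI vs 3aKO, 91 for 3bKI vs wt and 88 for 3bKI vs 3aKO. Of a further 100 shifted by 2, 99, 99, 97, 99 and 98 were recovered in that order. Genes left unchanged were called 17, 9, 10, 7 and 15 times, which is 7.42%, 4.27%, 4.93%, 3.37% and 6.38% of all calls. Real arrays differ from this setting, so the shares recovered do not say how many real changes of that size would be called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.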

Results

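Whole-genome expression was measured in 21 mouse livers or liver tumours at 12 months. E2f1, E2f3a and E2f3b are transcription factors of the E2F family, which regulate genes of the cell cycle. E2f3a and E2f3b are 2 products of the E2f3 gene. The groups were wt (n = 7), 3aKO (n = 5), 1KI (n = 5) and 3bKI (n = 4). Genotype and tumour status coincide in 1KI and 3bKI, so a difference between these groups and normal liver belongs to both together. Median log2 values per array lay between 5.48 and 5.53 in normalization 1 and between 5.34 and 5.43 in normalization 2.

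The E2f probe sets were read first, as a view of the targeted genes. E2f3 had a mean of 6.64 (SD 0.21, n = 5) in 3aKO and 6.84 (SD 0.18, n = 7) in wt, a log2 change of -0.19 ± 0.11 (SE) that did not pass limma's test (adjusted p = 0.700). In 1KI tumours E2f3 was at 7.41 (SD 0.28, n = 5), with a log2 change of 0.57 ± 0.13 against wt (adjusted p = 0.0780) and 0.77 ± 0.15 against 3aKO (adjusted p = 0.126). E2f1 showed a log2 change of 0.17 ± 0.11 in 1KI (adjusted p = 0.389) and 0.24 ± 0.11 in 3bKI against wt (adjusted p = 0.263). With every probe set tested, further E2f1 probe sets differed in sign in 1KI against wt, at 0.32 ± 0.15 (adjusted p = 0.273) and -0.16 ± 0.11 (adjusted p = 0.431). In 3bKI against wt they gave 0.30 ± 0.10 (adjusted p = 0.121) and 0.09 ± 0.09 (adjusted p = 0.644). In 3bKI tumours a second E2f3 probe set was higher than in 3aKO by 0.43 ± 0.10 when every probe set was tested (adjusted p = 0.0285), while the main E2f3 probe set gave 0.31 ± 0.13 (adjusted p = 0.155). Against wt this second probe set gave 0.27 ± 0.09 in 1KI (adjusted p = 0.162) and 0.40 ± 0.11 in 3bKI (adjusted p = 0.0775). A probe set need not lie in the deleted or inserted part of a gene, so these values do not check the alleles.

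The first comparison asked how livers without E2f3a differ from wt livers at an age when both are normal. Of single genes, 3 stood out when every probe set was tested. A probe set of Sugct, which encodes a mitochondrial CoA transferase, was lower in 3aKO by a log2 change of -2.86 ± 0.32 (adjusted p = 0.0171). Yae1d1 was higher by 1.45 ± 0.20 (adjusted p = 0.0490) and the zinc finger gene Zkscan8 by 1.02 ± 0.13 (adjusted p = 0.0220), and every 3aKO array lay beyond every wt array for all 3. These genes were chosen after their values were seen. They lie on the chromosome of E2f3, at 89, 85 and 63 measured genes from it, and a second probe set of Sugct gave 0.07 ± 0.12. With 1 probe set per gene, limma called 0 genes higher and 0 lower among 18193, with 1357 at an unadjusted p under 0.05 where 909.65 are expected by chance. The smallest adjusted p was 0.0980, for Yae1d1. The second normalization of the same arrays also gave 0, with 1360 at an unadjusted p under 0.05. Yae1d1 was called in a fit with all 3 groups and when wt replicate 2 was left out, and Etnppl was the 1 called without 3aKO replicate 3.

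Gene groups moved by small amounts in 3aKO livers. Genes of hepatocyte metabolism rose as lists: 23 of the 26 genes of urea cycle and amino acid catabolism (median log2 0.15, camera adjusted p = 1.76e-05), 15 of the 18 pericentral and Wnt pathway genes (0.17, adjusted p = 0.000131), 18 of the 22 NRF2 and glutathione genes (0.30, adjusted p = 4.42e-05) and 17 of the 22 bile acid genes (0.16, adjusted p = 0.00522) lay above 0. They had, with an estimated correlation, adjusted p = 0.347, adjusted p = 0.115, adjusted p = 0.280 and adjusted p = 0.115. Members with low p were Hgd, of tyrosine breakdown (0.39 ± 0.10), Gnmt, a glycine methyltransferase (0.34 ± 0.09), the Wnt feedback inhibitors Notum (0.49 ± 0.13) and Nkd1 (0.38 ± 0.10), the glutathione transferases Gsta4 (0.48 ± 0.11) and Gsta2 (1.73 ± 0.48), and Abcb11, the bile salt export pump (0.37 ± 0.10). None of these passed over all genes (adjusted p = 0.641 for each). Adjusted over the list alone, 2 urea cycle and amino acid, 3 pericentral, 2 NRF2 and 1 bile acid gene passed, all of them higher, beside 0 over all genes.

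Acute phase genes, which the liver secretes in inflammation, fell as a list in 3aKO, with 19 of 20 below 0 (median log2 -0.43, camera adjusted p = 2.17e-07, and adjusted p = 0.428 with an estimated correlation). Saa1 had a log2 change of -2.37 ± 0.72 and Hp, haptoglobin, -0.36 ± 0.11, both at adjusted p = 0.641 in limma. Over all genes 0 members were lower, and 4 were when adjusted over the list alone. Smaller calls upward were DNA replication and G1/S (35 of 44 above 0, median 0.11, adjusted p = 0.00204, and adjusted p = 0.630 with an estimated correlation), PPARalpha and fatty acid oxidation (20 of 25, 0.13, adjusted p = 0.0277, and 0.790 as the adjusted p with an estimated correlation) and stellate cell markers (19 of 22, 0.12, adjusted p = 0.00589, and 0.578 as the adjusted p with an estimated correlation). In these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone. Dnmt1 of the replication list had 0.29 ± 0.09. The first 2 of these had medians of -0.0614 and -0.0037 in females only. With sex as a covariate 9 of the 10 list calls of this comparison held, 7 upward and 2 downward, so that 1 upward call was lost.

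Sex-biased genes differed as well: female-biased liver genes had a median of 1.11 with 15 of 16 above 0 (camera adjusted p = 0.00300) and male-biased genes a median of -0.84 with 13 of 16 below 0 (adjusted p = 0.0354). With an estimated correlation the values were adjusted p = 0.790 and adjusted p = 0.870, and 0 members of either list passed over all genes or adjusted over the list alone. By Xist and Y-linked genes, 3 of 5 3aKO and 3 of 7 wt animals were female. With sex as a covariate the medians were 0.59 and -0.39, and both calls held at the preset correlation (adjusted p = 0.000342 and 0.0350). With an estimated correlation in that fit 0 lists were called (smallest adjusted p = 0.0509).

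E2f1 knock-in tumours were compared with wt liver, in a fit that does not include 3aKO liver. Interferon-induced genes were among the largest increases called without overlap: Usp18, which removes ISG15 from proteins, rose by a log2 change of 2.52 ± 0.39, Ifi27l2b by 2.46 ± 0.45, Oas1a by 2.21 ± 0.31 and Ifi27 by 1.85 ± 0.19. The AP-1 subunit Jun rose by 1.68 ± 0.25, from a mean of 7.41 (SD 0.29, n = 7) in wt to 9.08 (SD 0.66, n = 5). Targets of p53 rose with them, among them Phlda3 (1.62 ± 0.27), Plk2 (0.81 ± 0.14) and Ddit4l (0.79 ± 0.14). Igf2, a growth factor of fetal liver, rose by 1.38 ± 0.22 and Cd24a by 1.39 ± 0.25. Other large increases were Sparcl1, of the extracellular matrix (2.36 ± 0.28), Anxa5 (2.11 ± 0.39), the glutathione transferase Gstm3 (2.02 ± 0.35) and Mmp12, macrophage elastase (2.01 ± 0.28). Among called genes, decreases were fewer and smaller, with Meiob (-1.23 ± 0.22), Nmnat3 (-0.45 ± 0.08), Anp32a (-0.44 ± 0.08) and the methionine salvage enzyme Apip (-0.40 ± 0.06). Larger falls in the group mean were not called. Means in wt and 1KI were 7.79 (SD 0.36) and 5.96 (SD 1.26) for Cnmd, and 12.76 (SD 0.38) and 10.94 (SD 1.58) for Mup10. For Marco they were 7.76 (SD 1.46) and 5.63 (SD 1.04). These uncalled genes were chosen after their values were seen. In each of the called genes named here all 5 1KI arrays lay on 1 side of all 7 wt arrays, with adjusted p of 0.00485 (Ifi27) to 0.0484 (Ddit4l) in limma. Some of them also lay above wt in normal 3aKO liver, though none was called there. Means in wt, 3aKO and 1KI were 10.17, 11.14 and 12.19 for Gstm3, 4.32, 5.63 and 6.68 for Sparcl1, and 5.52, 6.31 and 6.91 for Cd24a. The 3aKO mean was not raised for Jun (7.41, 7.22 and 9.08) or Ifi27 (10.29, 10.21 and 12.14).

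In all, limma called 38 genes higher and 6 lower, with changes of at least 2-fold in 19 and 2 of them, and 3465 genes had an unadjusted p under 0.05. The count rests on which arrays are in the fit. Leaving out an array gave 6 higher and 0 lower (wt replicate 1), 6 and 0 (wt 2), 23 and 2 (wt 3), 2 and 0 (wt 4), 4 and 0 (wt 5), 26 and 2 (wt 6), 19 and 4 (wt 7), 56 and 13 (1KI 1), 49 and 10 (1KI 2), 16 and 1 (1KI 3), 25 and 2 (1KI 4), and 15 and 1 (1KI 5). The 2 genes left without wt 4 were Ifi27 and Sparcl1.

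Among the lists, 13 rose and 4 fell in 1KI against wt by camera. Interferon response genes lay above 0 for 21 of 24 (median log2 0.62, adjusted p = 9.66e-11, and adjusted p = 0.318 with an estimated correlation). There were 3 higher over all genes, Bst2 (1.12 ± 0.18) among them, and 13 adjusted over the list alone. Among p53 targets 18 of 22 lay above 0 (0.59, adjusted p = 9.66e-11, and adjusted p = 0.0494 with an estimated correlation). Of these 4 were higher over all genes and 14 adjusted over the list alone. Stellate cell and fibrosis markers followed with 21 of 22 above 0 (0.59, adjusted p = 1.71e-09, and adjusted p = 0.0494 with an estimated correlation). Pdgfrb, a receptor of stellate cells (0.76 ± 0.12), was the 1 called over all genes, and 12 were when adjusted over the list alone. These last 2 were the calls that held with an estimated correlation, and with sex as a further covariate neither did.

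Genes of cell division rose as groups without a single member passing over all genes. Of mitosis and G2/M genes 35 of 40 lay above 0 (median 0.42, camera adjusted p = 1.35e-11, and adjusted p = 0.318 with an estimated correlation). There were 17 higher when adjusted over the list alone and 0 over all genes, where Cdk1 had 1.26 ± 0.25 (adjusted p = 0.0640). Of DNA replication genes 36 of 44 did (0.22, adjusted p = 1.67e-06, and adjusted p = 0.332 with an estimated correlation). There were 5 higher when adjusted over the list alone and 0 over all genes, where Uhrf1 had 1.42 ± 0.33 (adjusted p = 0.0912). Immediate early genes had 14 of 15 above 0 (0.55, adjusted p = 2.48e-06, and 0.318 as the adjusted p with an estimated correlation). They had 1 and 5 members higher over all genes and adjusted over the list alone.

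Oncofetal and hepatocellular carcinoma markers rose with 13 of 22 above 0 (median 0.47, adjusted p = 0.00794), 2 of them over all genes and 8 adjusted over the list alone. NRF2 and glutathione genes rose with 17 of 22 (0.37, adjusted p = 2.74e-05), 1 over all genes and 9 adjusted over the list alone. The NRF2 list was also called higher in 3aKO against wt, and it was not called in 1KI against 3aKO with all arrays. Endoplasmic reticulum stress genes had 20 of 21 above 0 (0.37, adjusted p = 5.24e-05), with Atf3 at 1.72 ± 0.54 (adjusted p = 0.160), and cholesterol synthesis genes had all 20 above 0 (0.41, adjusted p = 0.00139), with Cyp51 at 0.76 ± 0.32 (adjusted p = 0.232). No member of either list passed over all genes or adjusted over the list alone. In the same order these 4 lists had, with an estimated correlation, adjusted p = 0.318, adjusted p = 0.318, adjusted p = 0.332 and adjusted p = 0.557. Cholangiocyte (0.27, adjusted p = 0.0223), endothelial (0.15, adjusted p = 0.0266) and glycolysis (0.07, adjusted p = 0.0266) genes rose by less, with adjusted p = 0.318, adjusted p = 0.318 and adjusted p = 0.332 with an estimated correlation. Plvap, of fenestrated endothelium, was the 1 member of these 3 lists called over all genes (1.00 ± 0.16). Adjusted over the list alone, 1 cholangiocyte gene was higher and 1 lower, and 1 endothelial and 1 glycolysis gene were higher.

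Lists of hepatocyte metabolism fell in 1KI against wt: urea cycle and amino acid catabolism with 24 of 26 below 0 (median -0.24, camera adjusted p = 0.00115), bile acids with 18 of 22 (-0.42, adjusted p = 0.0412) and PPARalpha and fatty acid oxidation with 19 of 25 (-0.32, adjusted p = 0.0113). Neutrophil markers fell too, with 12 of 13 below 0 (-0.22, adjusted p = 0.0113). They had, with an estimated correlation, adjusted p = 0.490, adjusted p = 0.557, adjusted p = 0.490 and adjusted p = 0.318. No member passed over all genes or adjusted over the list alone, and Haao, of tryptophan breakdown, had -0.69 ± 0.20 (adjusted p = 0.147). The 3 metabolic falls rest on 2 arrays, 1KI replicates 3 and 4, whose scores on the first principal component were 61.0 and 69.8, while the wt, 3aKO and other 1KI arrays lay between -17.0 and 5.08. Without both, 38 genes were higher and 1 lower (Csrp3), with 19 of the 38 shared with the fit of all arrays, and the medians were 0.00279 for urea cycle and amino acid catabolism, 0.0201 for bile acids and -0.0472 for PPARalpha, none of them called. In females only (2 1KI and 3 wt arrays), which leaves out both, bile acids were called higher (0.16, adjusted p = 0.0132). Neutrophil markers kept their fall without both (-0.24, adjusted p = 0.00693). The pericentral and Wnt pathway list, not called with all arrays (-0.35, adjusted p = 0.128), then had a median of 0.33 (adjusted p = 4.11e-08). List calls without both arrays or in females only were made at the preset correlation, and an estimated one was not tried there.

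Of the 17 list calls in 1KI against wt, 13 held without 1KI replicates 3 and 4, and the fourth lost beside the metabolic lists was glycolysis (0.10, adjusted p = 0.0966). Several rising lists kept their call at a smaller median: mitosis and G2/M at 0.16, immediate early genes at 0.21, interferon response at 0.39, endoplasmic reticulum stress at 0.16, cholesterol synthesis at 0.29, oncofetal markers at 0.36 and cholangiocyte markers at 0.0929. The medians of p53 targets, NRF2 and stellate markers were 0.65, 0.47 and 0.51. Lists called without both but not with all arrays, beside the pericentral pathway, were the acute phase response (-0.33, adjusted p = 0.000804), female-biased genes (0.91, adjusted p = 0.00821), T and NK cell markers (-0.19, adjusted p = 0.0281), erythroid markers (-0.21, adjusted p = 0.0281), pancreas acinar markers (-0.17, adjusted p = 0.0316) and the E2F and pocket protein family (0.21, adjusted p = 0.0430).

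**Figure D1:**
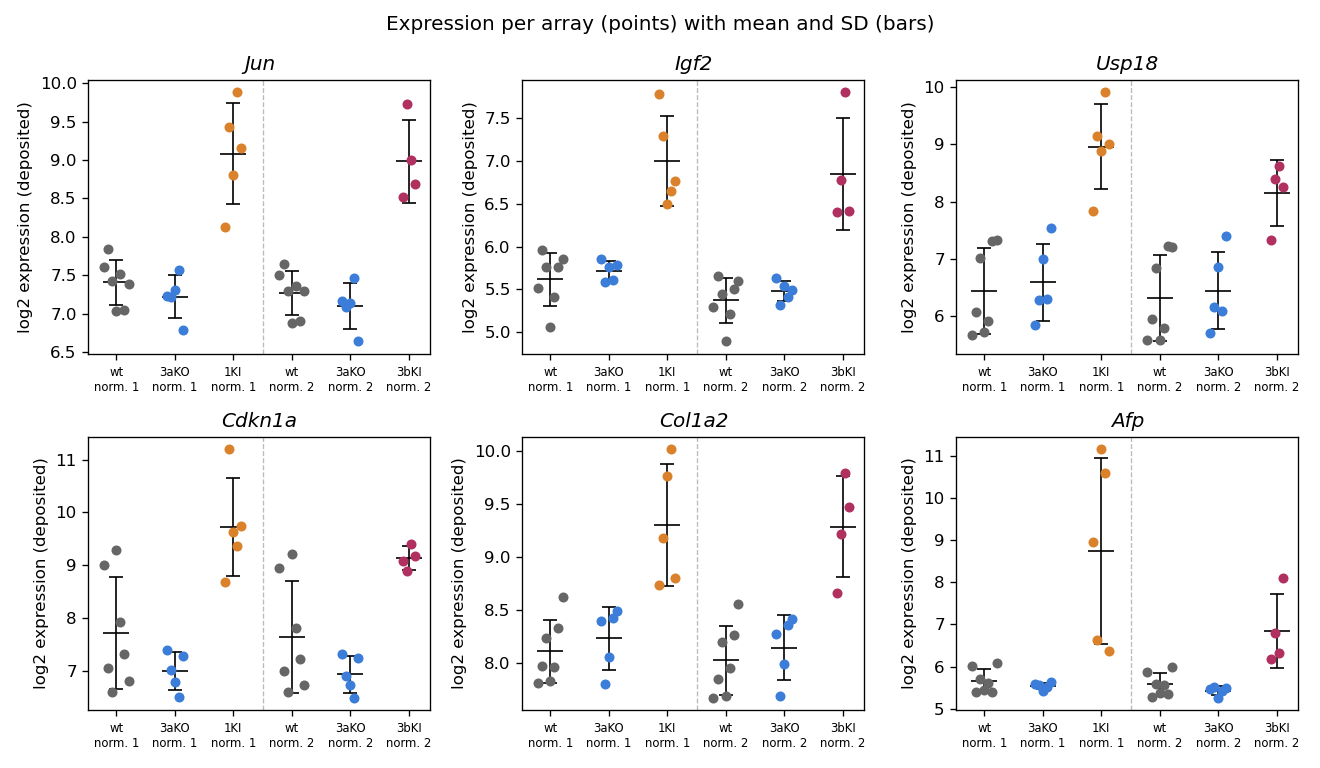
Log2 expression of 6 genes in each array, with each group's mean (horizontal bar) and SD (whiskers), on the 2 deposited normalizations (norm. 1 and norm. 2, separated by the dashed line). Jun lies above every wt and 3aKO array in the arrays of 1KI (mean 9.08) and 3bKI (mean 8.98), while Afp is spread from 6.37 to 11.2 among the 1KI tumours.

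The same tumours were also set against 3aKO liver, which lacks E2f3a. Interferon, p53 and AP-1 genes again lay higher in the tumours, though none passed over all genes. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had a log2 change of 2.73 ± 0.39, Oas1a 2.16 ± 0.32, Jun 1.86 ± 0.28, Oasl1 1.81 ± 0.27, Phlda3 1.72 ± 0.27 and Igf2 1.28 ± 0.22, each at adjusted p = 0.0788 and with all 1KI arrays above all 3aKO arrays. Afp, the fetal serum protein used as a marker of liver cancer, had 3.20 ± 0.86 (adjusted p = 0.213). limma called 0 genes higher and 0 lower, with 2550 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0603, for Ifi27. Ifi27 was called with quantile normalization, without dim genes, with every probe set tested (with Cpsf4l lower), with trend and robust, and with a sex covariate (with Phlda3 higher and Decr2 lower). Array weights gave 10 higher and 5 lower, the fit of all 3 groups 37 and 20, females alone 6 and 0, and the fit without 1KI replicates 3 and 4 gave 20 and 3. Leaving out 1KI replicate 1 gave 5 higher (Bst2, Cdkn1a, Ifi27, Jun and Oas1a) and 1 lower (Slc17a1), leaving out 1KI 2 gave 3 higher (Cdkn1a, Gria3 and Ifi27) and 1 lower, and leaving out 1KI 4 gave 1 higher (Tinag). These genes were chosen after their values were seen.

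By camera 12 lists rose and 6 fell in 1KI against 3aKO, and 0 held with an estimated correlation (lowest adjusted p = 0.223). Interferon response genes had 22 of 24 above 0 (median 0.58, adjusted p = 2.28e-13), p53 targets 18 of 22 (0.60, adjusted p = 1.69e-09), mitosis and G2/M 36 of 40 (0.43, adjusted p = 3.33e-11), stellate markers 18 of 22 (0.41, adjusted p = 4.49e-07) and oncofetal markers 14 of 22 (0.36, adjusted p = 0.00167). Adjusted over the list alone, 13, 12, 0, 7 and 7 of their members were higher, beside 0 over all genes. In the same order they had, with an estimated correlation, adjusted p = 0.267, 0.223, 0.387, 0.223 and 0.267. DNA repair and checkpoint genes rose slightly (0.15, adjusted p = 0.0173, and adjusted p = 0.490 with an estimated correlation), as did DNA replication genes (0.11, adjusted p = 0.00291, and adjusted p = 0.617 with an estimated correlation). Adjusted over the list alone 0 of the first and 2 of the second were higher, beside 0 over all genes, where Ccne1, cyclin E1, had 0.58 ± 0.12 (adjusted p = 0.141).

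Cholesterol synthesis (median 0.51, adjusted p = 4.62e-07), endoplasmic reticulum stress (0.36, adjusted p = 1.61e-07), acute phase (0.32, adjusted p = 0.00413), cholangiocyte (0.11, adjusted p = 0.0173) and immediate early genes (0.41, adjusted p = 0.000381) also rose as lists against 3aKO. With an estimated correlation these had adjusted p = 0.461, 0.444, 0.504, 0.267 and 0.461. Falling lists were urea cycle and amino acid catabolism (-0.48, adjusted p = 4.34e-07, with Cth at -1.02 ± 0.23), bile acids (-0.53, adjusted p = 0.000159), PPARalpha (-0.42, adjusted p = 5.05e-05), the pericentral pathway (-0.64, adjusted p = 0.0173), cytochrome P450 genes (-0.71, adjusted p = 0.0173) and T and NK cell markers (-0.14, adjusted p = 0.0173). Their adjusted p with an estimated correlation ran from 0.444 to 0.642. Beside 0 over all genes, members adjusted over the list alone were 1 cholesterol, 1 acute phase, 1 cholangiocyte, 3 immediate early and 1 PPARalpha gene higher, and 1 urea cycle and 12 PPARalpha genes lower. Without 1KI replicates 3 and 4, 12 of the 18 list calls held. Those lost were bile acids (-0.12, adjusted p = 0.151), the pericentral pathway (0.0850, adjusted p = 0.146), cytochrome P450 genes (-0.0580, adjusted p = 0.968), acute phase genes (0.0929, adjusted p = 0.2202), DNA repair (0.0998, adjusted p = 0.0797) and immediate early genes (0.0377, adjusted p = 0.126). The mitosis and urea cycle medians shrank to 0.20 and -0.15, both still called, and NRF2 genes were called higher (0.18, adjusted p = 0.00106). The immunoglobulin gene Ighm had -1.82 ± 0.38 (adjusted p = 0.141).

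E2f3b knock-in tumours were compared with wt liver in normalization 2. Fibrosis genes rose: the collagens Col3a1 by a log2 change of 1.71 ± 0.33, Col4a1 by 1.57 ± 0.26 and Col1a2 by 1.27 ± 0.21. Jun rose by 1.71 ± 0.22, from a mean of 7.27 (SD 0.29, n = 7) to 8.98 (SD 0.54, n = 4), and the antiproliferative gene Btg2 by 2.02 ± 0.38. Interferon-induced genes rose as in Ifi27l2b (2.40 ± 0.33), Usp18 (1.84 ± 0.38), Oas1a (1.55 ± 0.35) and Oasl1 (1.38 ± 0.26), and the fetal genes Igf2 (1.48 ± 0.24) and Dlk1 (0.67 ± 0.14) were higher too. The largest increases among called genes were Hsd3b1, of steroid synthesis (3.02 ± 0.52), Ly6d (2.67 ± 0.42), the protease inhibitor Slpi (2.63 ± 0.59) and Mtmr11 (2.53 ± 0.41).

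Some liver genes fell in the same tumours: the major urinary proteins Mup10 (-2.08 ± 0.39) and Mup3 (-1.42 ± 0.26), Tdo2, the first enzyme of tryptophan breakdown (-1.02 ± 0.19), Aass, of lysine breakdown (-0.64 ± 0.14), the bile acid ligase Slc27a5 (-0.54 ± 0.09) and Cyp2j5 (-0.74 ± 0.14). Mup3 is on the list of male-biased genes, and no 3bKI animal was read as male. With a sex covariate and the array of unclear sex left out, Mup10, Mup3, Tdo2, Aass, Slc27a5 and Cyp2j5 still lay at -1.44, -1.01, -0.72, -0.67, -0.54 and -0.61, though none passed (adjusted p = 0.0603 to 0.199). Of all 29 genes named for their call in this comparison, rising ones among them, 6 held in that fit. With a sex covariate all 29 held with that array as male and 4 with it as female, and 0 held in females only. The list of hepatocyte secretory and identity genes was not called (median -0.04, adjusted p = 0.242). Cnmd, chondromodulin (-2.54 ± 0.36), the Kupffer cell receptor Cd163 (-1.90 ± 0.39), Mcm10, of replication start (-1.39 ± 0.26), and the pocket protein gene Rbl2 (-0.77 ± 0.13) also fell. Among these genes the 4 3bKI arrays lay beyond all 7 wt arrays, except for overlaps in Oas1a, Oasl1 and Col3a1, and adjusted p ran from 0.00613 (Jun) to 0.0450 (Slpi).

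In total limma called 199 genes higher and 178 lower in 3bKI against wt, with changes of at least 2-fold in 72 and 23, and 3778 had an unadjusted p under 0.05. Their balance depended on scaling, since arrays centred on their median gave 197 higher and 548 lower. Signs of RNA quality moved with this comparison: the beta-actin 3'/5' log2 ratio was 0.802 on average (SD 0.0760, n = 4) in 3bKI and 1.10 (SD 0.248, n = 7) in wt, where replicates 6 and 7 had 0.876 and 0.654. By this ratio the RNA of 3bKI and of wt 6 and 7 reads as more intact, not less, than that of the other wt arrays. With the ratio as a covariate limma called 0 higher and 0 lower, though the 377 genes kept 0.822 times their median change and 100% their sign, and with wt 6 and 7 as the only control also 0 and 0, with 1025 at an unadjusted p under 0.05. Leaving wt 6 and 7 out gave 538 and 919. With a sex covariate and the array of unclear sex left out, 50 were higher and 17 lower, 39 of them shared with the fit of all arrays, while the same covariate gave 249 and 273 with that array as male and 32 and 25 with it as female. Females alone gave 11 and 5. Leaving out an array gave 69 higher and 28 lower (wt 1), 69 and 43 (wt 2), 77 and 44 (wt 3), 65 and 31 (wt 4), 69 and 50 (wt 5), 226 and 272 (wt 6), 354 and 494 (wt 7), 347 and 254 (3bKI 1), 127 and 37 (3bKI 2), 33 and 16 (3bKI 3), and 71 and 43 (3bKI 4).

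**Figure D2:**
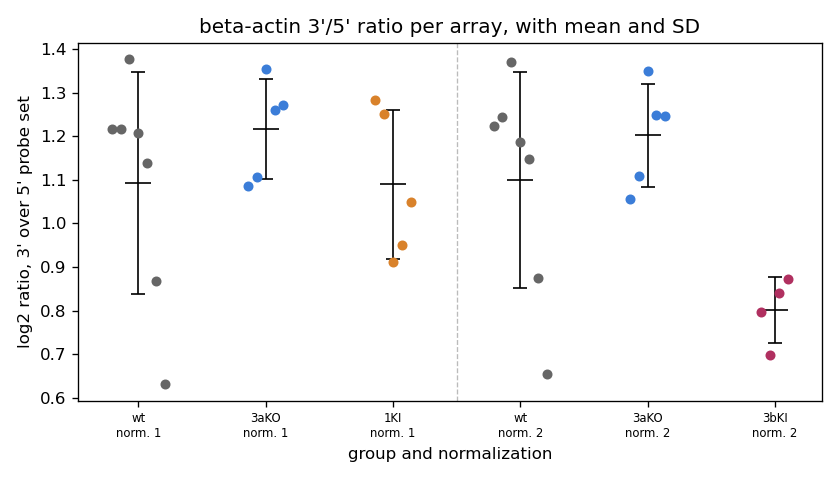
Log2 ratio of the 3' to the 5' beta-actin control probe set in each array (points), with mean and SD (bars), by group and deposited normalization. The 4 3bKI arrays lie between 0.698 and 0.874, below every 3aKO array and within the range of wt.

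By camera 15 lists rose and 5 fell in 3bKI against wt, and 0 held with an estimated correlation (lowest adjusted p = 0.0914). Stellate cell and fibrosis markers lay above 0 in 22 of 22 genes (median log2 0.83, adjusted p = 1.09e-11, and adjusted p = 0.0914 with an estimated correlation). Of these 7 were called over all genes and 17 adjusted over the list alone. Mitosis and G2/M genes had 38 of 40 above 0 (0.83, adjusted p = 1.31e-09, and adjusted p = 0.521 with an estimated correlation). Among them 0 were called over all genes and 0 adjusted over the list alone. Immediate early genes were above 0 in 15 of 15 (0.69, adjusted p = 6.89e-07, and adjusted p = 0.390 with an estimated correlation). Higher were 5 over all genes and 8 adjusted over the list alone. Interferon response genes were above 0 in 22 of 24 (0.61, adjusted p = 4.40e-06, and adjusted p = 0.521 with an estimated correlation), with 3 and 9 called in the same 2 ways. With a sex covariate and the array of unclear sex left out, the medians of these 4 lists were 0.81, 0.27, 0.68 and 0.29, all still called, but with adjusted p = 0.167, 0.681, 0.355 and 0.750 once the correlation was estimated too.

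Oncofetal markers rose with 19 of 22 above 0 (0.57, adjusted p = 2.29e-06, and adjusted p = 0.0914 with an estimated correlation), 3 over all genes and 7 adjusted over the list alone. The p53 targets rose with 19 of 22 (0.32, adjusted p = 0.000640, and adjusted p = 0.521 with an estimated correlation), 1 and 6 in that order. Urea cycle and amino acid catabolism fell with 24 of 26 below 0 (-0.27, adjusted p = 1.57e-05, and adjusted p = 0.427 with an estimated correlation), 2 over all genes and 5 adjusted over the list alone. Macrophage markers (0.35, adjusted p = 0.00667), neutrophil markers (0.30, adjusted p = 0.0183), B and plasma cell markers (0.30, adjusted p = 0.0176), endothelial markers (0.18, adjusted p = 0.0290) and cholangiocyte markers (0.23, adjusted p = 0.00580) rose. With an estimated correlation these had adjusted p = 0.541, 0.521, 0.521, 0.533 and 0.390. Among their members, Cldn7, a tight junction gene of bile duct cells (1.16 ± 0.19, adjusted p = 0.0183), and 1 B and plasma cell gene were called higher over all genes and Cd163, of the macrophage list, lower. Adjusted over the list alone, 4 macrophage, 1 B and plasma cell and 1 cholangiocyte gene were higher and 1 macrophage gene lower.

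Smaller list calls in 3bKI against wt were upward for NRF2 and glutathione (0.30, adjusted p = 0.0137), where Srxn1, sulfiredoxin, rose by 1.00 ± 0.11 (adjusted p = 0.00503), for cholesterol synthesis (0.46, adjusted p = 0.0141) and for DNA replication (0.13, adjusted p = 0.0162), whose 1 member called over all genes, Mcm10, was lower. They were downward for bile acids (-0.19, adjusted p = 0.0290), cytochrome P450 genes (-0.29, adjusted p = 0.0107) and the circadian clock (-0.47, adjusted p = 0.0186). Adjusted p with an estimated correlation ran from 0.390 to 0.679 for these 6. The NRF2 and DNA replication lists were also called higher in 3aKO against wt, and neither was called in 3bKI against 3aKO with all arrays. Over all genes 2 NRF2 genes were higher, and 1 replication, 1 bile acid and 1 cytochrome P450 gene lower. Adjusted over the list alone, 3 NRF2 and 1 cytochrome P450 gene were higher, and 1 replication, 3 bile acid and 3 cytochrome P450 genes lower. Male-biased liver genes had a median of -1.51 (adjusted p = 0.000111, and adjusted p = 0.521 with an estimated correlation) and female-biased genes 1.15 (adjusted p = 0.00489, and adjusted p = 0.562 with an estimated correlation), with no animal read as male in 3bKI and 4 of 7 in wt, and 1 male-biased gene was lower both over all genes and adjusted over the list alone. With a sex covariate and the array of unclear sex left out these medians were 0.40 and -0.11 and neither was called. Of single genes outside these lists, Atf3 (1.32 ± 0.26) and Pdk4 (1.44 ± 0.29) rose, both at adjusted p = 0.0317.

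Of these 20 list calls, 12 held with a sex covariate and the array of unclear sex left out, 12 with the beta-actin ratio as a covariate and 12 with wt replicates 6 and 7 alone as the control. DNA replication, bile acid, cholesterol synthesis and B and plasma cell lists were lost under all 3. In the first of these fits NRF2 (adjusted p = 0.0527), endothelial (adjusted p = 0.151) and both sex-biased lists were lost too. That fit differs in an array as well as in the covariate, and with the array kept as male 15 of the 20 held, with it as female 10. The beta-actin ratio and wt 6 and 7 alone both ended those of cytochrome P450, neutrophil and cholangiocyte genes, with the circadian clock lost under the former and macrophage markers under the latter. With it left out PPARalpha genes were called lower (-0.27, adjusted p = 0.00694, and adjusted p = 0.750 with an estimated correlation) and endoplasmic reticulum stress genes higher (0.27, adjusted p = 0.00669, and adjusted p = 0.645 with an estimated correlation). Endoplasmic reticulum stress and the acute phase response were called higher with wt 6 and 7 alone.

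In the fits of all arrays more genes were called in the E2f3b tumours against 3aKO liver (1671) than against wt (377). With the replicate block that order turned (50 and 694), and with the beta-actin ratio as a covariate both counts were 0. Cdkn1a rose by a log2 change of 2.20 ± 0.18, from a mean of 6.93 (SD 0.35, n = 5) to 9.13 (SD 0.22, n = 4), Jun by 1.89 ± 0.24 and Btg2 by 1.85 ± 0.49. Col5a2 (2.43 ± 0.27) and Col3a1 (1.55 ± 0.37) of the fibrosis list rose, as did the fetal genes Afp (1.42 ± 0.33) and Igf2 (1.37 ± 0.25) and the interferon-induced Oasl1 (1.88 ± 0.25) and Usp18 (1.704 ± 0.36). Mtmr11 (2.84 ± 0.35), Ly6d (2.84 ± 0.37) and the protease inhibitor A2ml1 (2.75 ± 0.45) had the largest increases among called genes without overlap. Apob, the apolipoprotein of very low density lipoprotein, fell by a log2 change of -1.24 ± 0.12, Cth, of cysteine synthesis, by -1.19 ± 0.26, Tdo2 by -0.92 ± 0.19, and Cebpa, a transcription factor of hepatocytes, by -0.43 ± 0.09. Etnppl (-2.49 ± 0.48), Cnmd (-2.55 ± 0.50), Cyp2b10 (-2.13 ± 0.48) and Cd163 (-1.69 ± 0.43) fell as well, and of the E2F and pocket protein family Rbl2 (-0.94 ± 0.13) and Tfdp2 (-0.52 ± 0.13) fell. The 4 3bKI arrays lay beyond the 5 3aKO arrays in these genes except Btg2, Col3a1 and Usp18, and adjusted p ran from 0.00178 (Cdkn1a) to 0.0458 (Btg2). For Etnppl the means in wt, 3aKO and 3bKI were 8.80, 10.67 and 8.18, and for Cyp2b10 7.17, 8.88 and 6.76. In both genes wt lay closer to 3bKI than to 3aKO, so most of the difference is between the normal livers.

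limma called 531 genes higher and 1140 lower in this comparison, 81 and 39 of them by at least 2-fold, and 5287 had an unadjusted p under 0.05. The counts depended on scaling, with 322 and 522 under quantile normalization and 328 and 1638 with arrays centred on their median. The replicate block gave 19 and 31. The beta-actin 3'/5' ratio was 0.698 to 0.874 in 3bKI and 1.06 to 1.35 in 3aKO, and with it as a covariate limma called 0 and 0. A sex covariate with the array of unclear sex left out gave 62 higher and 83 lower, with it as male 553 and 1181 and with it as female 41 and 115, and females alone gave 16 and 15. Leaving out 3aKO replicate 2 gave 207 and 519, 3aKO 3 227 and 617, 3aKO 4 126 and 364, 3aKO 5 157 and 429, 3bKI 2 306 and 631, 3bKI 3 220 and 464, and 3bKI 4 232 and 650.

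Between 3bKI and 3aKO 12 lists rose and 7 fell by camera, and 0 held with an estimated correlation (lowest adjusted p = 0.116). Urea cycle and amino acid catabolism fell in 25 of 26 genes (median -0.41, adjusted p = 5.54e-08, and adjusted p = 0.4931 with an estimated correlation), 8 of them over all genes and 12 adjusted over the list alone. Bile acid genes fell in 19 of 22 by sign (-0.45, adjusted p = 0.00166, and adjusted p = 0.555 with an estimated correlation), with 5 lower over all genes, such as the transporter Abcc3 (-1.42 ± 0.33) and Amacr (-0.81 ± 0.15), and 1 higher and 7 lower adjusted over the list alone. Stellate markers (0.76, adjusted p = 1.704e-06, and adjusted p = 0.4931 with an estimated correlation) rose in 8 genes over all genes and 11 adjusted over the list alone. Interferon response genes (24 of 24 above 0, 0.70, adjusted p = 2.96e-05, and adjusted p = 0.555 with an estimated correlation) rose in 4 and 9, and oncofetal markers (21 of 22, 0.33, adjusted p = 3.37e-05, and adjusted p = 0.116 with an estimated correlation) in 5 and 8. Cholesterol synthesis (0.63, adjusted p = 0.000718, and adjusted p = 0.555 with an estimated correlation) rose in 2 genes, Dhcr7 (0.85 ± 0.19) and Nsdhl (0.90 ± 0.23), and in 12 adjusted over the list alone.

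Further rising lists were mitosis and G2/M (0.72, adjusted p = 7.63e-06, with 0 members over all genes and 0 adjusted over the list alone), p53 targets (0.34, adjusted p = 0.00610), the acute phase response (0.47, adjusted p = 0.00184, with Lcn2 at 3.18 ± 0.87 at an adjusted p of 0.0496 and Serpina3n at 0.76 ± 0.12), immediate early genes (0.52, adjusted p = 0.00184), macrophage markers (0.39, adjusted p = 0.0217, with Lyz2 at 1.06 ± 0.27), neutrophil markers (0.36, adjusted p = 0.00555), B and plasma cell markers (0.20, adjusted p = 0.0194) and cholangiocyte markers (0.31, adjusted p = 0.0202). Their adjusted p with an estimated correlation ran from 0.4931 to 0.633. For Lcn2 the means in wt, 3aKO and 3bKI were 10.49, 8.10 and 11.28, and for Serpina3n 11.84, 11.07 and 11.83. In both genes wt lay closer to 3bKI than to 3aKO. Over all genes, then adjusted over the list alone, the members called higher were 3 and 5 for p53, 2 and 4 for acute phase, 4 and 6 for immediate early, 3 and 4 for macrophage, 2 and 5 for neutrophil, 2 and 2 for B and plasma cell and 1 and 1 for cholangiocyte genes. Called lower were 1 and 2 p53 targets and 1 and 1 macrophage genes. Further falling lists were the pericentral pathway (-0.53, adjusted p = 0.0137), PPARalpha (-0.26, adjusted p = 0.0202), cytochrome P450 genes (-0.54, adjusted p = 0.00184), male-biased genes (-1.10, adjusted p = 0.0476) and the circadian clock (-0.48, adjusted p = 0.0450), with adjusted p between 0.555 and 0.633 with an estimated correlation. Over all genes 1 pericentral and 3 cytochrome P450 genes were lower and 1 PPARalpha gene higher, and adjusted over the list alone 2, 4 and 1. With the beta-actin ratio as a covariate the medians of the mitosis, pericentral and circadian lists were -0.35, -0.15 and 0.53, each with its direction in camera reversed. With a sex covariate and the array of unclear sex left out, the medians of the mitosis, interferon and immediate early lists were 0.30, 0.46 and 0.10. Of the 19 list calls 14 held, and those lost were immediate early genes (adjusted p = 0.0537), macrophage and B and plasma cell markers (adjusted p = 0.0632 for each), the circadian clock (adjusted p = 0.0949) and male-biased genes (adjusted p = 0.644), while female-biased genes were called lower (-0.49, adjusted p = 0.0200, and adjusted p = 0.649 with an estimated correlation). With an estimated correlation none of the lists was called in that fit (smallest adjusted p = 0.352), and at the preset one 17 of the 19 held with that array as male and 15 with it as female. With the beta-actin ratio 10 of the 19 held, and beside the 3 reversed the bile acid, PPARalpha, cytochrome P450, cholangiocyte, male-biased and immediate early lists were lost. Called there but not without the ratio were T and NK cell, fatty acid synthesis and female-biased genes as higher and hepatocyte identity genes as lower.

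Some lists were called in no comparison in the fits of all arrays given above, though some were under alternatives. Their medians in the order 3aKO vs wt, 1KI vs wt, 1KI vs 3aKO, 3bKI vs wt and 3bKI vs 3aKO were 0.15, 0.12, -0.03, 0.02 and -0.03 for the E2F and pocket protein family, -0.01, -0.01, 0.02, -0.04 and -0.01 for hepatocyte secretory and identity genes, and 0.22, 0.15, 0.09, 0.06 and -0.17 for fatty acid synthesis. With a sex covariate and the array of unclear sex left out, fatty acid synthesis was called lower in 3bKI against wt (median -0.71, adjusted p = 2.32e-06, and adjusted p = 0.449 with an estimated correlation) and against 3aKO (-0.26, adjusted p = 0.0248, and adjusted p = 0.657 with an estimated correlation). Erythroid markers gave -0.07, -0.14, -0.09, 0.04 and 0.15, pancreas acinar markers -0.05, -0.12, -0.09, 0.01 and 0.00, and adipocyte and skeletal muscle markers -0.02, -0.08, -0.03, 0.05 and 0.07. Mean and median had opposite signs for hepatocyte identity genes in 1KI vs wt (mean 0.03), for adipocyte and muscle markers in 1KI vs wt (0.05) and 1KI vs 3aKO (0.09), and for the E2F family (-0.01) and erythroid markers (-0.00250) in 3bKI vs wt. The test pointed against the median for hepatocyte identity genes in 1KI vs wt, for the E2F family in 1KI vs 3aKO and 3bKI vs wt, and for fatty acid synthesis in 3bKI vs wt.

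**Figure D3:**
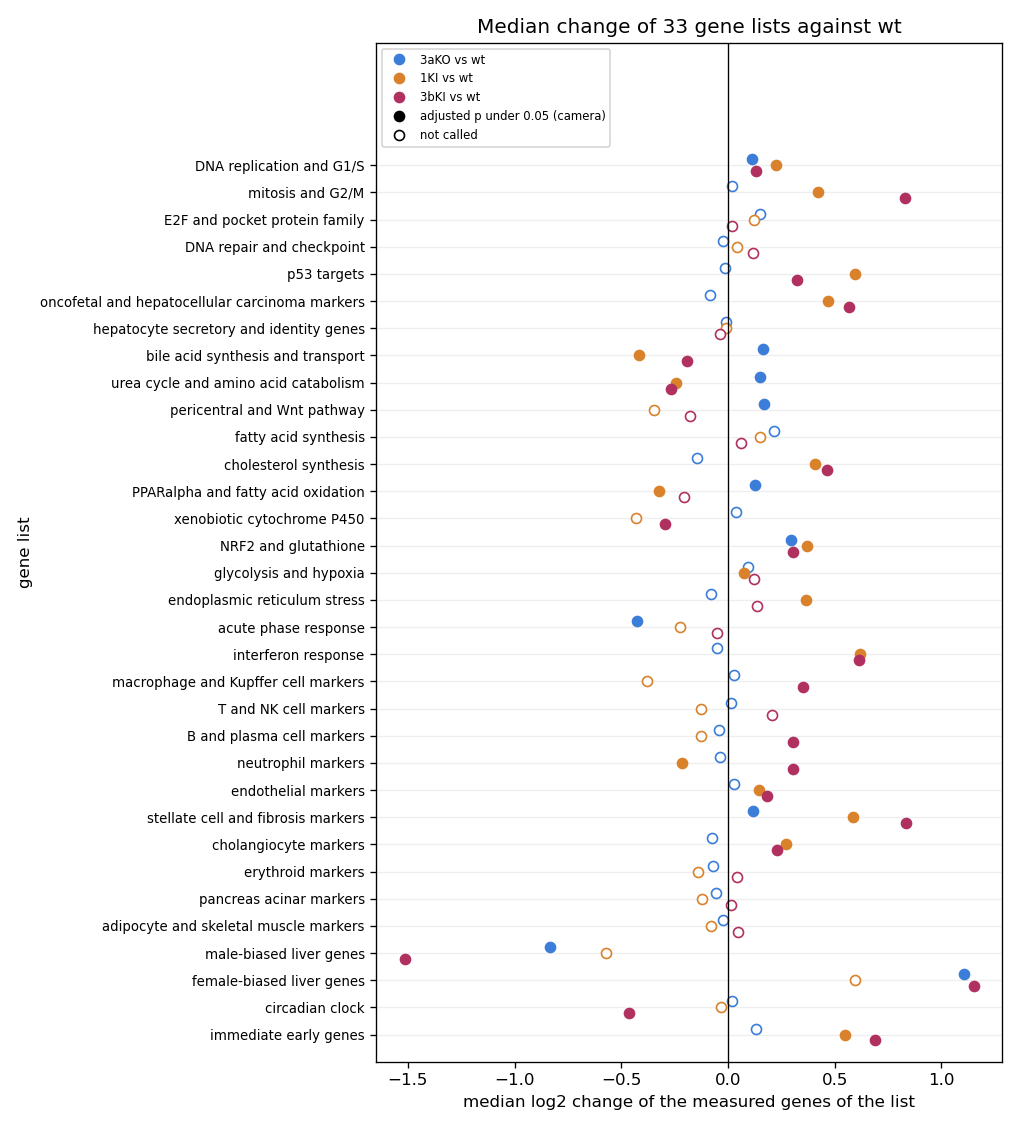
Median log2 change of the measured genes in each of 33 gene lists (vertical axis) for 3aKO, 1KI and 3bKI, each against wt (horizontal axis, log2). Filled points have an adjusted p under 0.05 in camera at the preset correlation; stellate cell and fibrosis markers have medians of 0.12, 0.59 and 0.83 in that order.

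The genes called in both tumour types against wt were compared as well. The same 19 genes rose in 1KI and in 3bKI, where independent lists would share 0.416. In both, 0 genes fell, where independent lists would share 0.0587, since only 6 genes were called lower in 1KI. That 0 thus does not show that the tumour types share no decreases. Among the 19 were Jun, Igf2, Usp18, Oas1a, Ifi27, Ifi27l2b, Anxa5 and Mmp12. Yae1d1, chosen after its values were seen, was another (1.498 in 1KI and 1.42 in 3bKI). It lay as high in normal 3aKO liver (1.45 against wt), so it is not particular to the tumours. The 7 wt arrays serve both comparisons and by themselves make fold changes alike: log2 changes correlated across genes with r = 0.560, and groups simulated without change gave a median r of 0.373 (0.318 to 0.420). The simulated noise was independent between genes and arrays, with no sex effect and no outlying array. Its range may thus be too narrow, and it does not decide whether 0.560 exceeds what the shared wt arrays give. Genes are not independent replicates. With the wt arrays split, 3 for one comparison and 4 for the other, r had a median of 0.419 over 35 splits (0.0502 to 0.619), and the median count of genes higher in both was 0. No test of 1KI against 3bKI was made.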

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

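The tests of sex composition, of 1KI replicates 3 and 4, and of the genes called with every probe set were chosen only after the result was seen, as were the fits with the beta-actin ratio as a covariate and with wt replicates 6 and 7 or 1KI replicates 3 and 4 left out or used alone. The test of sex composition replaced a test for an excess of sex-biased genes (one-sided Fisher exact p = 0.487 against wt and 0.999999 against 3aKO) after those values were seen, because genes that vary by sex within wt are hard to call. For the first test of genes near E2f3 a p over 0.05 was to count against a local effect, a bound that was wrong because the count seen, 4, lies above the 2.20 expected.

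A single array lay far from the rest of its group for 20 of 364 groups of values (85 genes and 6 array measures), where chance gives about 1 in 20, or 18.2. In wt these were Yae1d1 in replicate 2 (8.14), Col3a1 in replicate 7 (8.80), Col5a2 (8.78) and Oasl1 (8.07) in replicate 6, and Rbl2 in replicate 1 (9.31). In 3aKO they were Apip (8.89), Bst2 (9.88) and Meiob (7.17) in replicate 1, Rbl2 in replicate 3 (8.73), and Abcb11 (11.7) and Ddit4l (6.20) in replicate 5. In 1KI they were Atf3 (10.5) and Srxn1 (11.4) in replicate 4 and Lyz2 in replicate 5 (11.02). In 3bKI they were Srxn1 in replicate 1 (9.27), and Apip (8.59), Gsta2 (6.84), Mmp12 (6.62), Sult3a1 (11.8) and Xist (6.56) in replicate 2. That replicate holds 5 of the 6 in its group and is the array of unclear sex, with a Y-linked mean of 3.16.

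Splits of the arrays into groups of the same sizes were drawn, 100 per comparison with the real one included. For the 3 counts above 0 these came from 792, 330 and 126 possible splits, and no other split drawn called as many genes. That argues against chance for these counts but does not exclude it, since 1 of 100 is the lowest share that can be reached. In 1KI vs wt 1 of 100 splits, the real one, called as many genes (44, highest other 6), and so it was in 3bKI vs wt (377, highest other 108) and in 3bKI vs 3aKO (1671, highest other 1). The split with 108 set wt replicate 7 and 3bKI replicates 2, 3 and 4 against the rest. For 3aKO vs wt and 1KI vs 3aKO, where limma called 0 genes (1357 and 2550 at an unadjusted p under 0.05), 100 of 100 splits called as many, which a count of 0 fixes beforehand, so the splits (highest others 3 and 1) say nothing about chance there.

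The many genes called in 3bKI were weighed against sex and RNA quality. Without the array of unclear sex, a sex term left the median change of the called genes at 0.995 times its size against wt (0.630 to 0.628, SE 0.139 to 0.162) and 0.946 times against 3aKO (0.463 to 0.438, SE 0.110 to 0.119). These genes thus kept their change with a sex term. The test says no more about sex as a cause, since genes that vary by sex within a group are hard to call. The test it replaced had the same limit. The beta-actin ratio as a covariate left 0.822 times the change against wt (0.702 to 0.577, SE 0.135 to 0.160, calls from 377 to 0 as the SE grew and the change shrank), while against 3aKO it left 0.778 times (0.486 to 0.379, SE 0.106 to 0.254), where the ratio does not overlap between the groups and cannot be told apart from genotype. Of the 1671 genes called against 3aKO, 90.0% had the same sign in wt replicates 6 and 7 against wt 1 to 5, the highest of 21 pairs of wt arrays (next 85.6%, replicates 2 and 7). In 1KI vs 3aKO no gene was called, and the 1671 genes of lowest p gave 54.2% in normalization 1. The 2 shares thus come from unlike sets of genes. The GAPDH 3'/5' log2 ratio, a second sign of RNA quality, did not pair wt 6 and 7 with 3bKI. In normalization 2 it was 0.301 in wt 6 and 0.205 in wt 7, above and below the wt mean of 0.247 (SD 0.047, n = 7). It averaged 0.161 (SD 0.022, n = 4) in 3bKI and 0.205 (SD 0.047, n = 5) in 3aKO, with overlap between these groups. RNA quality or an array batch shared with wt 6 and 7 may carry part of the 3bKI calls, and tumour, genotype and that technical source stay open together.

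Genes near E2f3 were weighed as a local effect of the targeted locus: Sugct, Zkscan8 and Yae1d1, the 3 called in 3aKO vs wt with every probe set tested and chosen after their values were seen, all lie among the 200 measured genes nearest to E2f3, where 0.0331 would by chance (one-sided Fisher exact p = 1.32e-06). Against wt, the called Sugct probe set was lower by -2.96 ± 0.34 in 1KI and -2.64 ± 0.46 in 3bKI, and Yae1d1 higher by 1.498 and 1.42. In normalization 1 that Sugct probe set lay at 6.15 to 8.41 in wt arrays and 4.10 to 4.88 in 1KI arrays, and in normalization 2 at 3.78 to 5.77 in 3bKI arrays. The Sugct probe set of the main limma fits gave 0.07 ± 0.12 in 3aKO, -0.73 ± 0.25 in 1KI (adjusted p = 0.178) and -0.84 ± 0.17 in 3bKI (adjusted p = 0.0317). The large fall is thus that of 1 probe set and need not be that of the gene. Zkscan8 was higher in 1KI (0.96 ± 0.13) and not called in 3bKI (0.37 ± 0.14, adjusted p = 0.173), where it was lower than in 3aKO by -0.67 ± 0.10 (adjusted p = 0.00801), so it is not shared alike by the 3 genotypes. With 1 probe set per gene, 4 of the 200 nearest were among the 200 genes of lowest p (one-sided Fisher exact p = 0.180), which leaves the question open. The 1 neighbour low in p in both tumour comparisons, Yae1d1, had the same sign in all 3 genotypes (100%), too few to decide. DNA of another strain carried along with the targeted allele is a candidate explanation, since the mice are of mixed background, and a change made by the allele in cis stays open and was not tested.

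1KI replicates 3 and 4 lay apart from the other arrays of normalization 1 on the first principal component (61.0 and 69.8, other arrays -17.0 to 5.08, 32.3% of the variance). RNA quality as read from beta-actin stays open. The ratio was 0.911 and 0.951 in 1KI replicates 3 and 4, and lower in wt replicates 6 (0.867) and 7 (0.631). On the first component wt 6 scored -13.1, within the range of the other wt arrays, and wt 7 scored 3.24, highest of the wt arrays. A low ratio alone thus did not place a wt liver near 1KI 3 and 4, but so few arrays do not exclude it as a part of the cause. Fewer hepatocytes would raise the markers of all other cell types. Against wt the medians in these arrays were -0.274 for macrophage (interval -0.883 to 0.225), -0.0507 for T and NK cell (-0.211 to 0.0466), -0.105 for endothelial (-0.341 to 0.675) and 0.58 for stellate markers (0.241 to 1.52), and -0.00465 for hepatocyte identity genes (-0.0709 to 0.134). The intervals came from resampling the genes of a list 10000 times, so they measure spread among genes and not between animals. The values leave this explanation open, since 3 of the 4 intervals of other cell types include 0 and all rest on 2 arrays. A different stage or kind of tumour is a biological difference that could also set them apart and was not tested.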

How the results depend on the processing

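Alternatives added after the data were seen were fits within a sex, the sex covariate for 3bKI and for lists, the beta-actin ratio as a covariate, and fits with wt replicates 6 and 7 or 1KI replicates 3 and 4 left out or used alone. A result with no call whose sign turned counts as unchanged. Under the alternatives chosen beforehand, 1025 of 1137 values of named genes kept direction and side of the threshold, 97 lost and 15 gained a call, and 0 reversed; for lists these were 1469, 144, 53 and 0 of 1666. Under the added ones they were 334, 291, 2 and 1 of 628 for genes and 827, 171, 61 and 30 of 1089 for lists. With 1 array left out they were 909, 362, 7 and 0 of 1278 and 1626, 78, 78 and 0 of 1782. The number of arrays limits every count, and the cause was not tested for any change below unless stated.

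With 1 array left out, counts of genes higher and lower ranged from 0 to 1 and 0 to 0 in 3aKO vs wt, 2 to 56 and 0 to 13 in 1KI vs wt, 0 to 5 and 0 to 1 in 1KI vs 3aKO, 33 to 354 and 16 to 494 in 3bKI vs wt, and 126 to 509 and 364 to 931 in 3bKI vs 3aKO.

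3aKO vs wt (0 higher and 0 lower by limma, 1357 at an unadjusted p under 0.05): all probe sets tested gave 2 higher (Yae1d1, Zkscan8) and 1 lower (Sugct), all 3 groups in the fit 1 higher (Yae1d1), and the replicate block 1 higher (Socs2). In females only, the lists DNA replication and G1/S and PPARalpha and fatty acid oxidation had medians of -0.0614 and -0.0037.

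1KI vs wt (38 and 6): genes higher were 25 with quantile normalization, 220 with all 3 groups in the fit (93 lower), 61 with array weights, 1 (Ifi27) with the replicate block (0 lower), 76 with the sex covariate (17 lower), 12 in females only (1 lower), 7 in males only (1 lower), 58 with the beta-actin ratio as a covariate (12 lower), 7 with wt replicates 6 and 7 left out together (0 lower), and 1 (Ifi27) at an adjusted p under 0.01 (0 lower). With 1KI replicates 3 and 4 left out together 1 was lower (Csrp3), and the lists bile acid synthesis and transport and urea cycle and amino acid catabolism had medians of 0.0201 and 0.00279; in females only they had 0.16 (adjusted p = 0.0132, called higher) and 0.0532.

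1KI vs 3aKO (0 and 0 by limma, 2550 at an unadjusted p under 0.05): Ifi27 was the 1 gene higher with quantile normalization, with the lowest 40% of genes left out (fewer genes tested), with eBayes with trend and robust, and with all probe sets tested (1 lower, Cpsf4l). All 3 groups in the fit gave 37 and 20, array weights 10 and 5, the sex covariate 2 (Ifi27, Phlda3) and 1 (Decr2), females only 6 higher, and 1KI replicates 3 and 4 left out together 20 and 3. List medians in females only were 0.0756 for the pericentral and Wnt pathway, -0.0438 for xenobiotic cytochrome P450 and -0.0395 for the acute phase response; in males only they were -0.0182 for DNA replication and G1/S and 0.00421 for T and NK cell markers. Without 1KI replicates 3 and 4 the pericentral and Wnt pathway had 0.0850.

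3bKI vs wt (199 and 178): arrays centred on their median gave 197 and 548, all 3 groups in the fit 453 and 543, array weights 354 and 412, the replicate block 406 lower, wt replicates 6 and 7 left out together 538 and 919, and an adjusted p under 0.01 15 and 6. The beta-actin ratio as a covariate gave 0 and 0 by limma (1663 at an unadjusted p under 0.05), and wt replicates 6 and 7 alone as the control 0 and 0 (1025, with fewer arrays). The sex covariate gave 50 and 17 with the array of unclear sex left out, 249 and 273 with it as male, and 32 and 25 with it as female; females only gave 11 and 5. With it left out, at either correlation, medians were -0.0389 for DNA replication and G1/S, 0.14 for cholesterol synthesis and -0.11 for female-biased liver genes, and in females only -0.0389 and -0.11 for the first and last. With it as female they were 0.00625 for DNA replication, -0.0635 for male-biased and -0.24 for female-biased liver genes. Where a median keeps its sign, the direction of camera is what turned.

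3bKI vs 3aKO (531 and 1140): quantile normalization gave 322 and 522, arrays centred on their median 328 and 1638, the replicate block 19 and 31, an adjusted p under 0.01 15 and 30, females only 16 and 15, and the beta-actin ratio as a covariate 0 and 0 by limma (1088 at an unadjusted p under 0.05). The sex covariate gave 62 and 83 with the array of unclear sex left out, 553 and 1181 with it as male, and 41 and 115 with it as female. Male-biased liver genes had a median of -0.15 with it left out, at either correlation, and in females only, and -0.0342 with it as female. With the beta-actin ratio Cth had a change of 0.24, and the lists mitosis and G2/M, pericentral and Wnt pathway and circadian clock had medians of -0.35, -0.15 and 0.53.

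The overlap of the tumour comparisons, 19 genes higher in both, had a median of 0 with the wt arrays split 3 and 4 (fewer arrays) and was 0 at an adjusted p under 0.01. The arrays share only a replicate number: correlations of the 23 distinct same-number pairs ran from -0.469 to 0.443, with 9 above 0.1, and in no comparison were all pairs above 0.1 (most in 3aKO with 3bKI, 3 of 4).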

Other observations

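The tests by sex in this part were chosen after the data were seen. In normal liver (12 arrays of wt and 3aKO), limma called 201 genes higher and 260 lower in males than in females. A test of whether the genotype effect differs between the sexes called 0 genes by limma in 3aKO vs wt, 1KI vs wt and 1KI vs 3aKO, with 579, 1131 and 976 at an unadjusted p under 0.05 and smallest adjusted p of 0.999, 0.198 and 0.588. It could not be fitted for 3bKI, where no animal was read as male.

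Afp was spread widely among the tumours, with log2 values of 8.95, 6.64, 11.2, 10.6 and 6.37 in 1KI replicates 1 to 5 and 6.19, 6.80, 6.32 and 8.10 in 3bKI replicates 1 to 4. No 2 arrays were duplicates of each other (highest r = 0.995).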
